A study of Mus musculus with 124 samples.

How the data were processed

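Mice given human chorionic gonadotropin (hCG, the hormone used to trigger ovulation) were compared with unexposed mice (Ctrl). Per the labels, hCG females in natural estrus received 7.5 IU by intraperitoneal injection without prior priming. Their metaphase II oocytes were collected 14 h later, and those of Ctrl females the morning after housing with a vasectomised male, so mating and the time since ovulation were not matched between groups. Oocytes were freed of cumulus cells with hyaluronidase, blastocysts were flushed from the uterus on embryonic day 3.5, and dorsal dentate gyrus (dDG) was dissected from offspring aged 8 weeks after tribromoethanol anaesthesia and perfusion. RNA tables of 80 samples were used: 6 oocyte, 28 blastocyst and 6 dDG libraries per group. The other 44 samples, single-cell and reduced-representation bisulfite libraries, were not analysed here. Every column of values was matched to its sample by the labels. The numbers of the replicates do not pair Ctrl with hCG samples.

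The deposited oocyte table holds counts, whole numbers for each of 27016 gene symbols. The deposited dDG table holds expected_counts, estimated with decimals per RefSeq transcript, which were summed for each of 24409 symbols and rounded. The deposited blastocyst table, with 25239 symbols, holds a signal: estimated counts multiplied by a factor per library whose basis the labels do not give. Between 89.28% and 93.65% of a blastocyst library's values were whole multiples (tolerance 0.005) of a step that ran from 39.29 to 244.49 between libraries, so division by the column total removes the factor. Division by the step gave an estimated read number, used for depth, the low-count filter and the normalization factors. Per the labels, the authors named Trim Galore 0.6.4, Trimmomatic 0.32, STAR 2.7.6a, TopHat, Bowtie2, HTSeq 0.12.4 and SAMtools 1.19.1 with the builds mm10 and GRCm38, but not which of them made which table. Some oocyte and dDG symbols had been turned into dates (23 and 25 distinct names) and stayed unread. Gene positions on GRCm38 came from the supplied RefSeq table, which matched 84.17% of oocyte, 99.63% of blastocyst and 99.41% of dDG symbols.

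Oocyte and dDG counts were tested with edgeR 4.0.16 (robust quasi-likelihood F test) in R 4.3.3, after TMM normalization and the default low-count filter (at least 10 counts, 15 in total). Blastocyst values were tested with limma 3.58.1, as log2 of TMM-normalised CPM (counts scaled to the library total) plus 1, with a mean-variance trend and robust empirical Bayes. The plan for values other than counts had been log2 of the deposited value plus 1. It was replaced because deposited totals differed from 202452948 to 1218752121 between libraries. The replacement was chosen before the counts of genes under the literal form were seen, but when the higher deposited totals of hCG libraries were known. Counts under the literal form are given as an alternative. Every p was two-sided and adjusted by Benjamini-Hochberg over the genes of a table, with a threshold of 0.05 and no minimum fold. Each comparison is hCG against Ctrl, so a positive log2 fold change is higher in hCG. Errors of log2 fold changes are standard errors, and errors of CPM are SD.

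Before the data were examined, 41 gene lists were fixed for pathways and cell types. They were tested with camera (preset correlation 0.01) on voom values, or on the log2 values for blastocysts. Lists with fewer than 3 tested genes were left out: 2-cell and zygotic genome activation genes and gonadotropin signalling in blastocysts, mitochondrially encoded genes in blastocysts and dDG, and sex-linked genes in oocytes. Camera with an estimated correlation, fry and a permutation test of list means were the other set tests. Library measures were compared by two-sided permutation tests, exact over the 924 regroupings of 6 against 6 libraries and with 100000 resamples for blastocysts. Calls were compared between tables with Fisher's exact test. The difference of the hCG effect between oocytes and blastocysts was a Wald test of both log2 fold changes, taken from limma fits on log2 CPM plus 1 in both tables. There the hCG effect means the difference of hCG from Ctrl, which in oocytes also holds the unmatched mating and time since ovulation. DESeq2 had been planned for it and is an alternative, since the blastocyst values are not counts.

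Named genes followed a rule fixed before the data were examined. It took, per table, the 10 called genes with the largest rise and the 10 with the largest fall among those with a mean of at least 5 CPM, an informative symbol and at least 75% of hCG libraries on that side of the Ctrl median. It added up to 4 called members of each list by smallest p (the 2 most abundant where none passed), the DNA methylation enzymes, and up to 10 genes called in the same direction in 2 tables. Some members of lists were left out for length, and results for a few genes are not reported here.

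Alternatives were DESeq2 1.42.0, limma-voom, RLE normalization, no filter or a stricter filter, other thresholds, the replicate number as a block, the number of genes detected as a covariate, and Xist with Y-linked genes as covariates. Libraries more than 3 scaled median absolute deviations below the table median in genes detected or total were also left out (Ctrl 2 and 4 in oocytes, Ctrl 12 and 26 in blastocysts, Ctrl 2 in dDG), as was each oocyte and dDG library in turn. Alternatives added after the data were seen were edgeR on estimated blastocyst reads, unscaled deposited values, pseudocounts of 0.25 and 5 CPM, DESeq2 for the difference, list tests without the same libraries, and all blastocyst tests without the 5 libraries that hold at least 50 CPM of both Xist and Y-linked transcripts. For chance, 100 splits of the libraries per table were refitted. Plots were drawn with matplotlib 3.10.9.

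The pipeline was tested on simulated data with 200 genes changed by a log2 fold of 1. It called 48% of them in the right direction in an oocyte-like table, 84% in a blastocyst-like table and 78.5% in a dDG-like table. Unchanged genes made up 4.90%, 4.95% and 4.57% of its calls, among 9306, 10665 and 13786 genes tested. A list raised by 0.5 was called in each simulated table and 0 of the other 15, 18 and 26 lists were, but simulated genes vary independently. PCR reads are not independent molecules, and the depth of these libraries limits what can be seen in genes of few counts.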

Results

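Gene expression was measured in 3 materials from hCG-exposed and control mice: ovulated metaphase II oocytes, blastocysts and the dDG, the part of the hippocampus where granule neurons are born in the adult. The oocyte libraries held 2379861 to 6924189 counts and the dDG libraries 14991584 to 17859654 expected counts. The blastocyst libraries held an estimated 3043231 to 10859378 reads. Mean depth showed no difference past the threshold in any table: 4448557 ± 1650480 (SD, n = 6) in Ctrl and 4813712 ± 409403 in hCG oocytes (exact permutation test, adjusted p = 0.831), 6092699 ± 1932421 and 5606052 ± 1145831 in blastocysts (n = 28, permutation test, adjusted p = 0.260), and 16641000 ± 1060662 and 16839782 ± 541881 in dDG (n = 6, exact permutation test, adjusted p = 0.760). The labels do not state whether replicates are separate animals, so each p-value measures spread between samples.

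The first comparison asks whether exposure to hCG leaves ovulated oocytes with a different RNA content. Lzts1, a regulator of cell division, fell by 4.15 ± 0.27 on the log2 scale, from 387 ± 135 CPM to 21.9 ± 6.67 CPM (SD, n = 6; adjusted p = 1.07e-08), and lay below the Ctrl median in 6 of 6 hCG libraries. Tbl1xr1, a subunit of nuclear receptor corepressor complexes, rose by 2.64 ± 0.15 from 18.6 ± 1.499 to 117 ± 12.6 CPM (adjusted p = 1.75e-09). Eif4a1, the RNA helicase that starts translation, rose by 2.32 ± 0.16 from 115 ± 23.2 to 577 ± 107 CPM (adjusted p = 2.16e-08). The lists of ribosomal protein and oxidative phosphorylation genes were called lower by camera, with 4 of 59 and 2 of 64 members past the threshold downward, and neither call held with an estimated correlation (adjusted p = 0.355 for each). The kinase Mos, which holds the egg at metaphase II, and the maintenance methyltransferase Dnmt1 were lower. Over 9565 genes tested, 127 were higher and 255 lower in hCG oocytes.

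**Figure D1:**
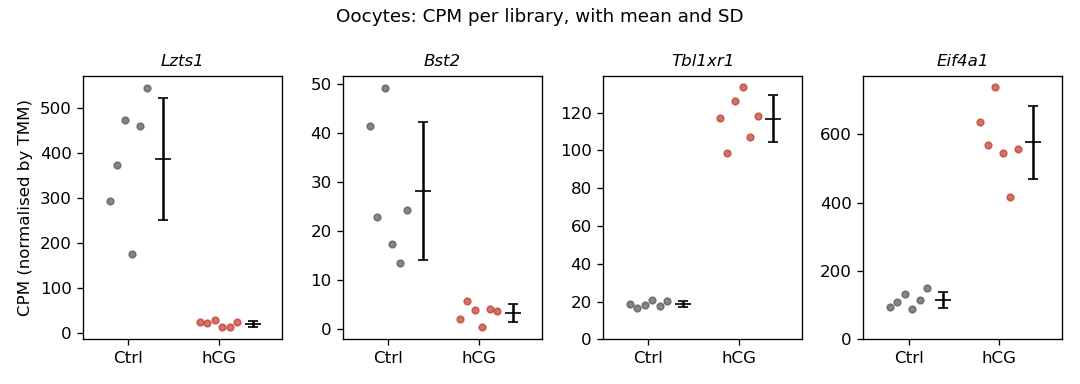
CPM of 4 genes in each oocyte library (points; 6 per group) with the mean and SD beside each group, on linear axes. Lzts1 ran from 176 to 545 CPM in Ctrl and from 13.6 to 29.8 CPM in hCG libraries, and Tbl1xr1 from 16.6 to 20.6 and from 98.8 to 133 CPM.

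The other large falls in oocytes included Trav7-6, a T cell receptor variable segment (-7.25 ± 0.48; 934 counts in all Ctrl libraries against 6 in hCG; similar segments can share its reads). They also included the interferon-induced antiviral factor Bst2 (-3.14 ± 0.43), the diacylglycerol kinase Dgkh (-2.78 ± 0.48), the RNA decay and splicing factor Lsm6 (-2.46 ± 0.40) and the pyrimidine-degrading enzyme Dpys (-2.34 ± 0.33). Tm2d1 (-2.32 ± 0.26), the cytokine signalling suppressor Socs2 (-2.28 ± 0.61), Krtap4-6 (-2.18 ± 0.45) and Fstl1 (-2.16 ± 0.57) completed the 10. Among the largest rises, the zinc finger gene Zfp990 went from 8 counts in all Ctrl libraries to 353 in hCG (5.21 ± 0.40). The synaptic adhesion gene Nlgn1 (4.45 ± 0.46), Plcl1 (4.29 ± 0.62), the germ-cell genes Tex15 (3.28 ± 0.49) and Tex19.2 (2.04 ± 0.35), Tpm4 (2.73 ± 0.50), Pgpep1 (2.26 ± 0.34) and Egfem1 (1.99 ± 0.40) rose as well. Lzts1 lies on chromosome 8 (69132659 to 69184249), Tbl1xr1 on chromosome 3 (22076253 to 22216594) and Eif4a1 on chromosome 11 (69666936 to 69672423). Bst2 also lies on chromosome 8, where large oocyte differences gathered. A difference in sequence between the donors of the groups therefore stays open for Lzts1 and Bst2.

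Of 59 cytosolic ribosomal protein genes measured in oocytes, 0 rose and 4 fell: Rps26 (-1.19 ± 0.24), Rps29 (-1.09 ± 0.23), Rps25 (-1.02 ± 0.24) and Rpl32 (-0.87 ± 0.20). Adjusted over the list alone, 10 fell, the median log2 fold change was -0.44, and the list was called (camera adjusted p = 2.80e-06; adjusted p = 0.355 with an estimated correlation). Of 64 nuclear oxidative phosphorylation genes, Ndufb5 rose (1.11 ± 0.28) and Ndufa4 (-1.57 ± 0.29) and Cox6a1 (-1.42 ± 0.39) fell. Adjusted over the list alone 1 rose and 18 fell, with a median of -0.40 (camera adjusted p = 2.68e-05; adjusted p = 0.355 with an estimated correlation). These 2 were the called lists among 16, and 0 were called with an estimated correlation.

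Single members moved in lists without a call. Of 28 spindle and cell cycle genes, 0 rose and 3 fell: Mos (-0.63 ± 0.12), the checkpoint protein Bub3 (-0.93 ± 0.18) and Aurkb (-1.48 ± 0.34). Of 21 oocyte-secreted and zona pellucida genes, Oog4 rose (0.72 ± 0.16) and 3 fell, among them Cd9, needed for sperm-egg fusion (-1.60 ± 0.28), and the zona protein gene Zp3 (-1.19 ± 0.28). Of 26 genes of DNA methylation and demethylation, Dnmt1 fell from 672 ± 200 to 391 ± 89.1 CPM (-0.78 ± 0.19, adjusted p = 0.0212) and the histone methyltransferase gene Ehmt1 fell (-0.77 ± 0.16), with 3 higher and 3 lower adjusted over the list alone. The de novo methyltransferase gene Dnmt3b had a log2 fold change of 0.84 ± 0.25 (adjusted p = 0.0726). The imprinted receptor gene Igf2r (-0.97 ± 0.20), the maternal complex gene Khdc3 (-1.499 ± 0.38) and the antioxidant genes Gclm (-1.18 ± 0.31) and Prdx1 (-0.68 ± 0.18) fell, and the estrogen receptor gene Esr2 (0.66 ± 0.16) and the chaperone gene Hsp90b1 (0.58 ± 0.15) rose. Of 3 markers of cumulus and granulosa cells measured, 0 passed.

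Ctrl libraries 2 and 4 detected few genes or reads (2379861 counts in Ctrl 2, 13123 genes in Ctrl 4). Without them 271 genes were higher and 324 lower, which moved the higher share from 33.2% to 45.5%, and leaving out any 1 library gave 70 (without Ctrl 5) to 292 (without Ctrl 4) higher and 167 (without Ctrl 3) to 365 (without Ctrl 4) lower genes. DESeq2 called 265 higher and 430 lower. Apart from the replicate block, 13 of the 42 named calls (Aurkb, Cox6a1, Dnmt1, Esr2, Fstl1, Gclm, Hsp90b1, Khdc3, Ndufa4, Ndufb5, Prdx1, Socs2 and Zp3) ended under another setting or without 1 library, with an adjusted p of up to 0.176.

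The second comparison asks whether embryos of exposed females still differ at the blastocyst stage. Of 19 targets of the tumour suppressor p53 and apoptosis genes 8 were higher (camera adjusted p = 1.55e-04; adjusted p = 0.205 with an estimated correlation). Among them Cdkn1a, which stops the cell cycle, rose by 1.00 ± 0.21 on the log2 scale, from 163 ± 88.0 to 299 ± 153 CPM (SD, n = 28; limma adjusted p = 0.00124), and lay above the Ctrl median in 27 of 28 hCG libraries. Bax, which opens mitochondria in apoptosis, rose by 0.92 ± 0.17 from 93.8 ± 47.3 to 158 ± 35.6 CPM (adjusted p = 2.96e-04; 28 of 28). The de novo methyltransferase gene Dnmt3b fell from 151 ± 50.7 to 96.8 ± 25.3 CPM (-0.61 ± 0.11, adjusted p = 2.82e-04; below the Ctrl median in 27 of 28). Tspan8, a surface protein gene of the trophectoderm, the outer layer that forms the placenta, fell from 859 ± 471 to 413 ± 283 CPM (-1.24 ± 0.30). Over 10848 genes tested, 942 were higher and 821 lower in hCG blastocysts.

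**Figure D2:**
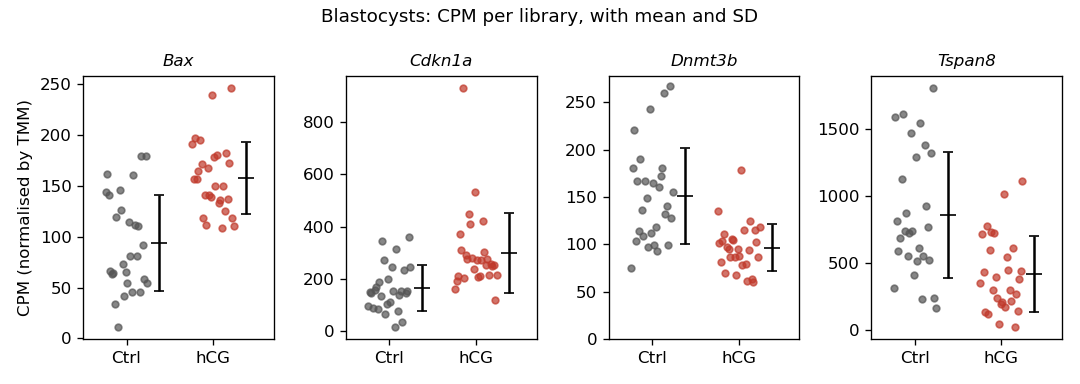
CPM of 4 genes in each blastocyst library (points; 28 per group) with the mean and SD beside each group, on linear axes. Bax ran from 10.9 to 180 CPM in Ctrl and from 108 to 246 CPM in hCG libraries, and Dnmt3b from 75.5 to 267 and from 60.0 to 179.0 CPM.

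Of 19 p53 target and apoptosis genes, 8 rose and 0 fell, among them the death receptor gene Fas (1.00 ± 0.26) and Ccng1 (0.54 ± 0.13). Adjusted over the list alone 12 rose, with a median log2 fold change of 0.43 (camera adjusted p = 1.55e-04; adjusted p = 0.205 with an estimated correlation). Of 27 genes of DNA methylation and demethylation, 0 rose and 8 fell, among them Uhrf1, which brings Dnmt1 to replicated DNA (-0.52 ± 0.13), the methyl-DNA binding gene Mbd2 (-0.67 ± 0.20), Dnmt3a (-0.43 ± 0.13) and the demethylating dioxygenase gene Tet1 (-0.37 ± 0.13). Adjusted over the list alone 11 fell, with a median of -0.25 (camera adjusted p = 3.04e-04; adjusted p = 0.131 with an estimated correlation). Ehmt1 fell (-0.38 ± 0.10), and Dnmt1 had a log2 fold change of -0.32 ± 0.12 (adjusted p = 0.0565).

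Of 20 trophectoderm markers, 0 rose and 8 fell, among them the transcription factor genes Gata2 (-0.88 ± 0.21), Tfap2a (-0.77 ± 0.18) and Eomes (-0.69 ± 0.17) and the growth factor receptor gene Fgfr2 (-0.53 ± 0.12). Tested over this list only, 3 rose and 8 fell, with a median of -0.30 (camera adjusted p = 0.00664; adjusted p = 0.536 with an estimated correlation). Of 76 nuclear oxidative phosphorylation genes, 1 rose and 17 fell, such as Ndufb5 (-0.55 ± 0.11) and Ndufs4 (-0.48 ± 0.12). With p adjusted within the list, 1 rose and 22 fell, with a median of -0.19 (camera adjusted p = 1.71e-08; adjusted p = 0.583 with an estimated correlation). These 4 were the called lists among 19. Of 17 inner cell mass and epiblast markers, the pluripotency gene Nanog rose (0.58 ± 0.19) and the secreted phosphoprotein gene Spp1 fell (-2.16 ± 0.54), with a camera adjusted p of 0.682 for the list. Of 17 primitive endoderm markers 2 rose, such as Amn (1.09 ± 0.24), and 3 fell, such as the laminin genes Lama1 (-1.09 ± 0.32) and Lamb1 (-0.69 ± 0.20). Of 4 markers of uterine, stromal and blood cells, the class II antigen gene H2-Ab1 rose (0.98 ± 0.26), and all 4 had positive log2 fold changes (median 0.48; camera adjusted p = 0.205, fry adjusted p = 0.0213, permutation adjusted p = 0.0227).

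The largest rises were in the polo-like kinase genes Plk5 (1.66 ± 0.33) and Plk2 (1.57 ± 0.26), the chromatin architecture gene Hmga1 (1.60 ± 0.41), the bicarbonate transporter gene Slc4a5 (1.54 ± 0.31), the ephrin gene Efna3 (1.48 ± 0.28), the peptide transporter gene Tap1 (1.35 ± 0.27), Cnppd1 (1.31 ± 0.24), the RNA-binding gene Rbm38 (1.28 ± 0.22), Tgoln2 (1.26 ± 0.40) and the small chaperone gene Hspb8 (1.24 ± 0.25). The largest falls were, besides Spp1, Tspan8 and Lama1, in BC051665 (-2.00 ± 0.69), the placental gene Plac1 (-1.24 ± 0.36), the glutathione transferase gene Gsta1 (-1.22 ± 0.37), Gulp1 (-1.19 ± 0.25), Csta1 (-1.18 ± 0.22), the metalloprotease gene Adam19 (-1.13 ± 0.25) and Akr1c21 (-1.12 ± 0.37). Cdkn1a lies on chromosome 17 (from 29090979), Bax on chromosome 7 (from 45461695) and Dnmt3b on chromosome 2 (from 153649411).

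More genes were detected in hCG than in Ctrl blastocysts (13549 ± 335 against 12968 ± 798; permutation test, adjusted p = 1.20e-04; 25 of 28 hCG libraries above the Ctrl median). In 5 of 28 hCG libraries (1, 3, 4, 22 and 23) and 0 of 28 Ctrl libraries, both Xist (69.4 to 165 CPM) and Y-linked transcripts (126 to 173 CPM) were present (Fisher's exact test, p = 0.0515), while Xist reached at most 23.3 CPM in the other libraries with Y-linked transcripts. The labels do not say that each library is a single embryo. Without these 5 libraries 667 genes were higher and 480 lower, the same 4 lists were called by camera at its preset correlation, and the difference in genes detected was 584 (permutation test, adjusted p = 0.00159), and the share of the 50 most abundant genes no longer passed (-1.09 points, adjusted p = 0.0639). With all libraries, 0 of the 4 lists were called with an estimated correlation (adjusted p = 0.131 to 0.583). Fry and the permutation of list means did call the p53 list (adjusted p = 2.34e-04 and 1.90e-04). They also called the DNA methylation list (adjusted p = 1.17e-04 and 1.90e-04) and the trophectoderm list (adjusted p = 0.0258 and 0.0349). These 2 tests ask whether the members differ between groups, not whether they differ more than other genes. The 50 most abundant genes took a smaller share of reads (18.3% ± 1.43 against 19.5% ± 2.25; permutation test, adjusted p = 0.0169). With the 10 most abundant the difference was -0.63 points (permutation p = 0.115). With the number of genes detected as a covariate, 337 genes were higher and 437 lower. Of the 942 higher and 821 lower genes of the main fit, 259 and 326 were still called. Deposited totals were higher in hCG libraries, and without scaling to the total the median of all genes was 0.49 higher in hCG, 3655 genes were higher and 15 lower (99.6% higher against 53.4%). In edgeR on estimated reads 576 were higher and 972 lower (37.2% higher). Apart from unscaled values, 18 of the 58 named calls (Akr1c21, BC051665, Cdk1, Dnmt3a, Gsta1, Hmga1, Insig1, Lamb1, Mbd2, Mest, Nanog, Ndufb5, Ndufs4, Plac1, Tet1, Tfap2a, Tgoln2 and Ubr3) ended under another setting, with an adjusted p of up to 0.274.

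The third comparison asks whether the brains of offspring differ in adulthood. Rbm3, an RNA-binding protein gene induced by cold, fell from 139 ± 9.47 to 50.7 ± 10.9 CPM (-1.46 ± 0.11; SD, n = 6; edgeR adjusted p = 5.70e-05; below the Ctrl median in 6 of 6 hCG libraries), and so did the related cold-inducible gene Cirbp (-1.15 ± 0.10; adjusted p = 5.70e-05). Of 26 immediate early genes, which neurons switch on when active, 12 were lower (camera adjusted p = 2.88e-07; adjusted p = 0.308 with an estimated correlation). Among them the transcription factor gene Npas4 fell from 18.9 ± 2.31 to 9.20 ± 2.08 CPM (-1.03 ± 0.14; adjusted p = 5.62e-04). Of 24 cholesterol synthesis genes 11 were lower (camera adjusted p = 8.61e-12; adjusted p = 0.191 with an estimated correlation). Among them Hmgcs1 fell from 198 ± 22.1 to 137 ± 20.5 CPM (-0.54 ± 0.10; adjusted p = 0.00602). Pmepa1, an inhibitor of transforming growth factor beta signalling, rose from 30.5 ± 2.21 to 76.9 ± 18.5 CPM (1.33 ± 0.13; adjusted p = 1.55e-04). Over 13874 genes tested, 648 were higher and 443 lower in hCG dDG.

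**Figure D3:**
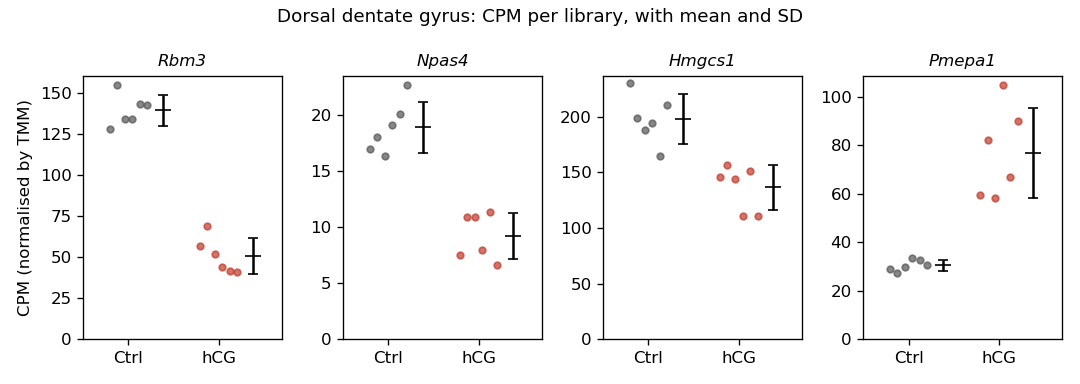
CPM of 4 genes in each dDG library (points; 6 per group) with the mean and SD beside each group, on linear axes from 0. Rbm3 ran from 128 to 154 CPM in Ctrl and from 41.1 to 69.1 CPM in hCG libraries, and Pmepa1 from 27.5 to 33.4 and from 58.4 to 105 CPM.

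Of 24 cholesterol synthesis genes, 0 rose and 11 fell, among them Mvd (-0.52 ± 0.09) and Msmo1 (-0.45 ± 0.08). Over its members alone, 17 fell, and the median was -0.33 (camera adjusted p = 8.61e-12; adjusted p = 0.191 with an estimated correlation). Of 26 immediate early genes, 1 rose and 12 fell, among them Egr4 (-0.85 ± 0.08), Egr1 (-0.85 ± 0.14), Junb (-0.61 ± 0.08) and Gadd45b (-0.72 ± 0.10). Within the list alone, 2 rose and 13 fell, and the median was -0.30 (camera adjusted p = 2.88e-07; adjusted p = 0.308 with an estimated correlation). Beside them, markers of the choroid plexus, ependyma and meninges had a median log2 fold change of 2.09 with 0 of 16 passing. Their most abundant member, the transthyretin gene Ttr, stood at 27.1 ± 24.7 CPM in Ctrl and 1521 ± 3674 CPM in hCG (adjusted p = 0.132), a mean carried by hCG library 6.

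Of 14 dentate granule neuron markers, 4 rose, among them the transcription factor genes Prox1 (0.36 ± 0.09) and Glis3 (0.53 ± 0.10) and Plk5 (0.50 ± 0.13), and the channel gene Trpc6 fell (-0.37 ± 0.10). Tested over this list only, 6 rose and 1 fell (camera adjusted p = 0.00873; adjusted p = 0.946 with an estimated correlation). Of 22 presynaptic vesicle genes, 0 rose and 1 fell. With p adjusted within the list, 2 fell (camera adjusted p = 0.00226; adjusted p = 0.946 with an estimated correlation). Of 20 GABAergic synapse genes, Gabbr2 (0.22 ± 0.06) and the GABA-synthesising Gad1 (0.19 ± 0.05) rose and the receptor subunit gene Gabra5 fell (-0.33 ± 0.05), while 18 of the 20 had negative log2 fold changes. Over its members alone, 2 rose and 3 fell (camera adjusted p = 0.0111, lower; adjusted p = 0.946 with an estimated correlation).

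Of 17 microglia markers, the complement genes C1qa (0.29 ± 0.08) and C1qb (0.34 ± 0.09) and Tmem119 (0.31 ± 0.08) rose and 0 fell. Within the list alone, 4 rose (camera adjusted p = 0.0276; adjusted p = 0.947 with an estimated correlation). Interferon response genes (14; median 0.41) and nuclear oxidative phosphorylation genes (76; median -0.04) were called with 0 members passing, also adjusted over the list alone (camera adjusted p = 0.0276 for each; adjusted p = 0.947 with an estimated correlation for each). These 8 were the called lists among 27, and 0 were called with an estimated correlation. Other markers of tissue composition had no call: of 19 oligodendrocyte genes 16 had negative log2 fold changes (median -0.23, camera adjusted p = 0.413), the precursor genes Olig2 (0.43 ± 0.09) and Cspg4 (0.49 ± 0.09) were among 3 that rose and the myelin gene Opalin fell (-1.16 ± 0.27), and of 18 endothelial and mural genes 17 had positive log2 fold changes (median 0.48, camera adjusted p = 0.0656) and Ly6c1 rose (0.84 ± 0.16).

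The other large falls were in the channel gene Ano2 (-1.54 ± 0.24), the stress-induced transcription factor gene Atf3 (-1.24 ± 0.35), the potassium channel gene Kcnb2 (-0.92 ± 0.12) and the heat shock genes Hspa1a (-1.25 ± 0.25) and Hspa1b (-0.98 ± 0.24), near-identical copies whose reads cannot be parted with certainty. The other large rises were in the activin antagonist gene Fst (1.25 ± 0.14), the integrin gene Itga11 (1.22 ± 0.29), Serinc2 (1.18 ± 0.22), Klhl33 (1.15 ± 0.17), the amino acid transporter gene Slc38a5 (1.14 ± 0.30), the metalloprotease gene Adam8 (1.13 ± 0.18), Kirrel (1.11 ± 0.18), the sterol carrier gene Stard5 (1.09 ± 0.10) and Rhbdl3 (1.07 ± 0.16). Rbm3 lies on chromosome X (from 8138975), Npas4 on chromosome 19 (from 4984353) and Hmgcs1 on chromosome 13 (from 119690351).

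Y-linked transcripts stood above Xist in 6 of 6 libraries of each dDG group, so all were male by this measure, yet the Y-linked Uty was higher in hCG (0.59 ± 0.09, adjusted p = 0.00134) and the Y-linked Eif2s3y had a log2 fold change of -0.30 ± 0.09 (adjusted p = 0.0509; 0 of 6 hCG libraries above the Ctrl median). With Xist and the sum of Y-linked genes as covariates, which together explained 49.0% of the variance of group, 29 genes were higher and 15 lower, and Rbm3, Cirbp, Egr4, Npas4, Junb, Kcnb2, Fst, Pmepa1, Stard5, Rasa1 and Ubr3 were the named calls that passed. Without Ctrl library 2, which had the lowest total (14991584), 404 were higher and 277 lower, and leaving out any 1 library gave 395 (without Ctrl 6) to 684 (without Ctrl 5) higher and 254 (without Ctrl 6) to 547 (without Ctrl 5) lower. Apart from those covariates and the replicate block, 15 of 55 named calls (Atf3, C1qa, C1qb, Gabbr2, Gad1, Hsp90b1, Hspa1b, Itga11, Per1, Plin4, Plk5, Prox1, Slc38a5, Tmem119 and Trpc6) ended under another setting or without 1 library, with an adjusted p of up to 0.210.

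The last comparisons ask whether the 3 materials share changes. The cohesin loader gene Mau2 was higher in oocytes (0.99 ± 0.22) and dDG (0.36 ± 0.06). In blastocysts and dDG, Rbm3 (-0.50 ± 0.12 in blastocysts), Hmgcs1 (-0.64 ± 0.15), the condensin gene Smc2 (-0.48 ± 0.08 and -0.47 ± 0.09), the Ras regulator gene Rasa1 (-0.67 ± 0.13 and -0.45 ± 0.07), the ubiquitin ligase gene Ubr3 (-0.50 ± 0.12 and -0.37 ± 0.05) and the deubiquitinase gene Usp34 (-0.40 ± 0.09 and -0.23 ± 0.05) fell in both. The thioesterase gene Acot1 (0.85 ± 0.17 and 0.58 ± 0.09) and Hsf1, the master regulator of heat shock genes (0.89 ± 0.16 and 0.46 ± 0.09), rose in both. No overlap of calls passed the test: of 9338 genes tested in blastocysts and dDG, 42 were higher in both against 34.8 expected, and 32 lower in both against 21.5 expected (Fisher's exact test, adjusted p = 0.306 and 0.0655). Without the 5 blastocyst libraries with both Xist and Y-linked transcripts, oocytes and blastocysts shared fewer calls than expected (0 higher against 4.72 and 3 lower against 11.2; adjusted p = 0.0444 and 0.0424).

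Between oocytes and blastocysts, 1 gene was higher in both against 6.74 expected and 10 were lower in both against 18.5 expected (Fisher's exact test, adjusted p = 0.0655 and 0.0691, over 7177 genes). Between oocytes and dDG, 5 were higher in both against 3.86 expected and 5 lower in both against 6.56 expected (adjusted p = 0.527 and 0.688, over 7669 genes). At an adjusted p under 0.1 for each gene, both overlaps of blastocysts with dDG passed (105 higher in both against 82.3 expected, adjusted p = 0.0213, and 77 lower against 56.1, adjusted p = 0.0207; Fisher's exact test). The difference of hCG from Ctrl itself differed between oocytes and blastocysts for 1084 of 7177 genes, and of 290 genes called in oocytes 125 had the same sign in blastocysts. In oocytes that difference also holds the unmatched mating and time since ovulation, so a different response to hCG cannot be told apart from these. Dnmt3b is an example, with 0.88 in oocytes, where edgeR did not call it, and -0.61 in blastocysts on the same log2 scale (difference -1.49 ± 0.27, Wald test, adjusted p = 4.22e-06).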

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

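The tests of control libraries with few genes detected for the oocyte differences, all tests of the trophectoderm markers, those of libraries with both Xist and Y-linked transcripts, and the count of large differences by chromosome, were chosen after those results were seen, and all 3 patterns were picked from results already seen, with the other tests written before their own values were known. For trophectoderm cell number, the rule first written argued against that explanation, since both upper bounds lie under the size of the trophectoderm difference; the condition that lists with called members both ways decide nothing was added after that outcome was seen.

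Of 210 groups of 6 libraries examined for the named genes and library measures, 11 held a library far from the other 5, where chance gives about 1 in 20. In oocytes, hCG library 2 was high in Esr2 (6.36 log2 CPM plus 1, others 5.94 to 6.03), Ctrl library 5 was low in Lsm6 (2.65, others 4.74 to 5.45) and hCG library 3 was high in Trav7-6 (0.90, others 0 to 0.27). In dDG, Ctrl library 1 was low in Egr4 (4.20, others 4.36 to 4.45), Fst (2.73, others 3.32 to 3.57) and Slc38a5 (2.01, others 2.89 to 3.25). Ctrl library 5 was high in Rasa1 (6.83, others 6.36 to 6.51) and low in genes detected (16018, others 16291 to 16418). Among hCG dDG libraries, number 6 was high in Ttr (13.14, others 2.53 to 5.27), number 4 was low in Olig2 (4.12, others 4.44 to 4.57) and number 1 was low in Stard5 (4.10, others 4.45 to 4.65).

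In oocytes the hCG effect also holds the unmatched mating and time since ovulation. For 44 named genes the hCG effect differed between oocytes and blastocysts, by a Wald test of the difference (blastocyst minus oocyte, log2, ± standard error; adjusted p from 2.47e-52 for Tbl1xr1 to 0.0478 for Lamb1). It was higher in blastocysts for Lzts1 (4.38 ± 0.34), Tm2d1 (2.13 ± 0.27), Bst2 (3.95 ± 0.57), Socs2 (2.6998 ± 0.47), Rbm38 (1.37 ± 0.27), Lsm6 (2.04 ± 0.40), Hsf1 (1.16 ± 0.23), Aurkb (1.67 ± 0.35), Bub3 (1.00 ± 0.21), Cd9 (1.23 ± 0.28), Hmga1 (2.23 ± 0.50), Ndufa4 (1.34 ± 0.31), Dnajb1 (0.90 ± 0.21), Rps26 (1.08 ± 0.25), Rps29 (1.03 ± 0.26), Cnppd1 (1.25 ± 0.32), Igf2r (0.92 ± 0.24), Slc4a5 (1.48 ± 0.40), Zp3 (1.33 ± 0.37), Rpl32 (0.75 ± 0.21), Rps25 (0.88 ± 0.25), Khdc3 (1.23 ± 0.36), Gclm (1.35 ± 0.40), Bax (1.01 ± 0.32), Cox6a1 (1.20 ± 0.38) and Mest (0.80 ± 0.27). It was lower in blastocysts for Tbl1xr1 (-2.89 ± 0.18), Eif4a1 (-2.45 ± 0.18), Zfp990 (-3.50 ± 0.32), Nlgn1 (-3.85 ± 0.49), Tpm4 (-2.47 ± 0.37), Ndufb5 (-1.65 ± 0.29), Dnmt3b (-1.49 ± 0.27), Pgpep1 (-1.74 ± 0.34), Mki67 (-1.28 ± 0.27), Rasa1 (-1.35 ± 0.30), Hsp90b1 (-0.82 ± 0.19), Tex19.2 (-1.59 ± 0.38), Mau2 (-0.99 ± 0.26), Usp34 (-0.90 ± 0.24), Mbd2 (-1.15 ± 0.31), Uhrf1 (-0.66 ± 0.18), Insig1 (-0.77 ± 0.26) and Lamb1 (-0.69 ± 0.26).

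The first pattern is the size of single changes in oocytes: 44 called genes had an absolute log2 fold change of at least 2, 20 higher and 24 lower, with a median of 2.81. Control libraries with few genes do not account for it, since without Ctrl 2 and 4 the median was 2.86 and 39 of the 44 passed. A variant shared by the donors of eggs and embryos, and acting alike in both, does not account for all of it. Of the 22 genes tested in blastocysts 45.5% (10 genes, 95% exact interval 24.4% to 67.8%) had the same sign there. That interval leaves room for such a variant in part of these genes, and genes not tested in blastocysts stay open. Neighbouring genes reached by 1 change in sequence or copy number stay open: 19.5% of the 41 genes with a position had another within 1 Mb, above the upper bound of 14.6% from 10000 random sets (median 4.88%, p = 0.0150). Of these 41 genes 8 lie on chromosome 8, which holds 5.40% of the genes tested (Fisher's exact test, adjusted p = 0.0281), so a difference in sequence between the oocyte donors of the groups may contribute to part of the pattern. Lzts1 and Bst2 lie on that chromosome, so this caution applies to both. Exposure to hCG, and the mating and timing that differed with it, were not tested apart.

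The second pattern is higher p53 targets with lower DNA methylation genes and trophectoderm markers in hCG blastocysts, with mean log2 differences of 0.41, -0.19 and -0.30 (95% interval -0.51 to -0.09). Control libraries with few genes are not the whole cause, since without Ctrl 12 and 26 these were 0.37 (0.20 to 0.53), -0.20 (-0.29 to -0.11) and -0.31 (-0.53 to -0.10), and nor is the number of genes detected, with which as a covariate they were 0.30 (0.11 to 0.48), -0.23 (-0.32 to -0.14) and -0.37 (-0.60 to -0.14). Nor are the 5 hCG libraries with both Xist and Y-linked transcripts, without which they were 0.44 (0.24 to 0.63), -0.19 (-0.28 to -0.10) and -0.25 (-0.46 to -0.05). Fewer trophectoderm cells cannot be told apart from lower expression: the inner cell mass list (mean -0.19; -0.47 to 0.08) holds both Nanog, which rose, and Spp1, which fell, and the primitive endoderm list (-0.18; -0.42 to 0.07) holds both Amn, which rose, and Lama1, which fell. The trophectoderm list was itself mixed: 7 of its 20 log2 fold changes were positive, and 3 members rose when adjusted over the list alone. A response of the embryo to hCG exposure of the mother may underlie the pattern, a hypothesis found and tested on the same libraries, while a difference in stage or collection, and mixing in libraries where both parts have the same sex, stay open and untested.

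The third pattern is lower immediate early and cholesterol synthesis genes in hCG dDG. Choroid plexus or meningeal tissue is not the whole cause: with the mean of its markers as a covariate the immediate early genes differed by -0.39 (95% interval -0.58 to -0.20; -0.39 without it) and the cholesterol genes by -0.28 (-0.40 to -0.17; -0.31 without it). With the mean of the oligodendrocyte markers as a covariate the cholesterol genes differed by -0.30 (-0.43 to -0.17), so that mean does not account for the difference. The list holds the precursor genes Olig2 and Cspg4, which rose, and the myelin gene Opalin, which fell. Its mean therefore cannot decide on fewer oligodendrocytes. Handling between anaesthesia and collection cannot be told apart from exposure, since the cold-inducible Rbm3 fell with the immediate early genes and their relation within groups, the only one computed, was loose (r = 0.32, permutation p = 0.160, 95% interval -0.39 to 0.79; rho = 0.38, permutation p = 0.223; r = 0.37 without the 2 libraries farthest from the median). Xist and Y-linked genes as covariates, which explained 49.0% of the variance of group, also bear on this pattern. With them the cholesterol genes Hmgcs1, Msmo1 and Mvd no longer passed (edgeR adjusted p = 0.238, 0.187 and 0.156). Their log2 fold changes stayed negative (-0.43, -0.38 and -0.45). Nor did Egr1, Gadd45b and Per1 pass (edgeR adjusted p = 0.128, 0.0874 and 0.277), with log2 fold changes of -0.79, -0.63 and -0.36, while Npas4, Egr4 and Junb passed. Covariates that share this much variance with group can widen the error of its effect. The lost calls alone therefore cannot show that these covariates account for the pattern. What these covariates stand for in male libraries was not tested. Exposure of the mother to hCG before conception remains an untested biological explanation, and temperature or handling may be another.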

How the results depend on the processing

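In this part, edgeR on estimated blastocyst reads, unscaled deposited values (the literal form of the plan), the pseudocounts, DESeq2 for the difference, leaving out the 5 blastocyst libraries with both Xist and Y-linked transcripts, and list tests without libraries of few genes were chosen after the data were seen. No gene called in the main analysis was called with the opposite sign under any setting, and 29 of 42 named oocyte calls, 22 of 58 in blastocysts and 11 of 55 in dDG passed under every setting tried (minimum fold aside) and, in oocytes and dDG, without each library. In oocytes (127 higher, 255 lower), DESeq2 called 265 and 430, the genes-detected covariate gave 216 higher, and leaving out Ctrl 2 and 4 gave 271 higher. An adjusted p under 0.1 gave 236 and 410, a log2 fold of at least 1 gave 55 and 152, and an unadjusted p under 0.05 gave 839 and 969, each by a looser or stricter limit. Leaving out each library gave 70 to 292 higher and 167 to 365 lower: 80 higher without Ctrl 3, 292 without Ctrl 4, 70 without Ctrl 5, 80 without hCG 1, 78 without hCG 4, and 167 lower without Ctrl 3. In blastocysts (942 and 821), the genes-detected covariate gave 337 and 437, edgeR on estimated reads 576 higher, leaving out the 5 libraries with both Xist and Y-linked transcripts 480 lower (667 higher), a log2 fold of at least 1 gave 51 and 18, and an unadjusted p under 0.05 gave 1779 and 1549. Unscaled deposited values gave 3655 and 15, since deposited totals were higher in hCG libraries, ended 32 named calls, and reversed 17 genes to small positive log2 values: Atp5pb 0.16, Cdk1 0.11, Edem1 0.0227, Ehmt1 0.0365, Glrx 0.13, Hspe1 0.14, Jade1 0.00187, Lrp2 0.0897, Msmo1 0.0499, Ndufv2 0.0637, Ooep 0.0115, Rps13 0.20, Rps20 0.15, Tet1 0.0598, Tpx2 0.0425, Ube3a 0.0453, Usp34 0.0300. The share of the 10 most abundant genes differed by -0.63 points (adjusted p = 0.173; -1.19 and 0.0169 for the 50, or -1.09 and 0.0639 without those 5 libraries). In dDG (648 and 443), DESeq2 called 712 lower, the replicate block gave 388 and 195 although the numbers do not pair samples (1 of 6 pairs correlated above 0.1), and Xist with Y-linked genes as covariates, which together explained 49.0% of the variance of group, gave 29 and 15. An adjusted p under 0.1 gave 1042 and 790, a log2 fold of at least 1 gave 25 and 21, and an unadjusted p under 0.05 gave 1754 and 1570. Leaving out each dDG library gave 395 to 684 higher and 254 to 547 lower: 404 and 277 without Ctrl 2, the library of lowest total, 416 and 266 without Ctrl 3, 395 and 254 without Ctrl 6, and 287 lower without hCG 4. With an estimated correlation 0 lists were called in oocytes, blastocysts and dDG (2, 4 and 8 by the preset one). In blastocysts fry and the permutation of list means also called 4, but without nuclear oxidative phosphorylation (adjusted p = 0.0605 and 0.0578; 0.202 with the genes-detected covariate) and with the uterine, stromal and blood list (0.0213 and 0.0227). Fry called 5 in oocytes, with ribosomal protein and nuclear oxidative phosphorylation genes among them (adjusted p = 0.0177 for each). The permutation of list means also called these lists in oocytes (adjusted p = 0.0346 and 0.0462). In dDG fry called 2, cholesterol synthesis (adjusted p = 0.00230) and immediate early genes (adjusted p = 0.00339). The permutation of list means called 0 in dDG, and the genes-detected covariate gave 7 in blastocysts. In dDG that permutation could not call a list that alone reached its smallest possible p, 0.00216, which adjusts to 0.0584 over 27 lists. Cholesterol synthesis stood at that limit, so the 0 decides nothing about it. Immediate early genes had a permutation p of 0.00433 (adjusted p = 0.0584). Of the 6 overlaps 2 passed at an adjusted p under 0.1 per gene and another 2, with fewer shared calls than expected, without those 5 libraries, against 0. The effect differed between oocytes and blastocysts for 1084 genes, 1073 under a stricter filter and 910 by DESeq2. Where no cause is named, the cause was not tested. Replicate numbers did not pair oocytes or blastocysts either (2 of 6 and 3 of 28 pairs above 0.1).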

Other observations

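No test of this part was chosen after its result was seen. In hCG blastocysts, genes of the epithelial seal and of fluid transport moved both ways: of 23 measured, 3 rose and 6 fell, among them the desmosomal cadherin gene Dsg2 (-0.69 ± 0.12, below the Ctrl median in 28 of 28 hCG libraries) and the angiomotin gene Amot (-0.62 ± 0.14), with a camera adjusted p of 0.205. Of 30 genes of DNA replication and mitosis, 0 rose and 4 fell, such as Mki67 (-0.63 ± 0.13), the topoisomerase gene Top2a (-0.58 ± 0.12) and Cdk1 (-0.32 ± 0.10; camera adjusted p = 0.592). Cholesterol synthesis lost 4 of 24 genes, such as Hmgcs1 and Insig1 (-0.66 ± 0.19; camera adjusted p = 0.211). Of 13 heat shock chaperone genes, Hsf1 and the co-chaperone gene Dnajb1 (0.64 ± 0.11) rose and 3 fell, among them Hsph1 (-0.47 ± 0.11; camera adjusted p = 0.935). Of 26 imprinted genes, Mest rose (0.73 ± 0.21) and 5 fell, with the long noncoding RNA Kcnq1ot1 at -0.79 ± 0.17 (camera adjusted p = 0.224). Of 76 cytosolic ribosomal protein genes, 1 rose and 2 fell (median -0.04; camera adjusted p = 0.211).

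In hCG dDG, of 24 genes of the unfolded protein and integrated stress response, 4 rose, among them Hsp90b1 (0.72 ± 0.16), Calr (0.62 ± 0.14) and Canx (0.30 ± 0.07), and 2 fell, such as Atf4 (-0.31 ± 0.06; camera adjusted p = 0.411). Of 15 heat shock chaperone genes, Hsf1 rose and 3 fell, with Dnajb1 at -0.76 ± 0.16 beside Hspa1a and Hspa1b (camera adjusted p = 0.641). Of 41 glutamatergic receptor and scaffold genes, 3 rose, among them the metabotropic receptor gene Grm2 (0.68 ± 0.10) and the kainate receptor gene Grik3 (0.53 ± 0.07), and 0 fell (camera adjusted p = 0.941). Of 19 glucocorticoid response genes, the lipid droplet gene Plin4 rose (1.62 ± 0.43) and the clock gene Per1 fell (-0.34 ± 0.09; camera adjusted p = 0.837). DNA methylation genes (27; 1 rose, 2 fell), adult neurogenesis genes (19; 1 rose), interneuron markers (15; 0 passed), astrocyte markers (14; 0 passed) and imprinted genes (34; 0 passed) had camera adjusted p-values of 0.837, 0.970, 0.274, 0.487 and 0.393.

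Splits of single libraries treat each library as independent, although the labels do not state whether replicates are separate animals. Samples that share an animal would not be independent, and the splits cannot allow for that. If the libraries are independent, chance can be excluded for the counts of genes at the limit of 100 splits per table, since the real split alone, 1 of 100, reached its count. In oocytes it gave 127 higher and 255 lower genes, and the highest other split gave 1 and 1. In blastocysts it gave 942 and 821 against 14 and 22, and in dDG 648 and 443 against 1 and 1. Chance cannot be excluded for the number of lists called: 45 of 100 splits of the oocyte libraries gave at least the real 2 (highest other 4), 44 of the blastocyst libraries at least 4 (highest other 9) and 64 of the dDG libraries at least 8 (highest other 15). The effect differed between oocytes and blastocysts for 1084 genes, which 1 of 100 joint splits reached, the real one (highest other 201). Each other joint split removes the effect from both materials at once. These splits therefore speak only against no effect in either material, and they do not test an equal effect in both. For overlaps past the threshold the real number was 0, which 100 of 100 splits reach whatever they hold (highest other 0), so the splits decide nothing there.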
